A study of Danio rerio with 6 samples.

How the data were processed

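Transcript levels were measured by RNA sequencing in 3 wild-type and 3 homozygous pikfyve-delta8 zebrafish samples. Per the labels' protocols, RNA was purified with a Qiagen kit, mRNA was isolated and fragmented, and amplified cDNA was circularized before sequencing. Whether the library keeps strand is not given in the sources used here, so reads of a gene and an antisense partner cannot be told apart. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build GRCz11, without saying in which order or with which settings they were used.

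One table of 25645 genes was used. Per the file headers, the deposited table holds read counts, FPKM and TPM for each sample, with gene symbols and NCBI gene identifiers. The deposited counts are estimated counts of the kind RSEM gives, since 10.7% to 11.6% of the values of a sample are not whole numbers (tolerance 0.005). The deposited FPKM values scale the estimated counts by transcript length and depth. The deposited TPM values were not tested. Group averages that the authors deposited were not used, and no column belonged to a sample outside the series. All genes carried a symbol, and 20 symbols occurred more than once. Fractional counts arise where a read fits several genes and is divided between them, so genes with near-identical copies, such as opsins, globins and protocadherins, are uncertain where noted. Genomic positions are not given, because the annotation at hand is of another build (GRCz12tu). It was used only to see which genes lie on one chromosome or side by side, and 92.5% of the gene identifiers matched it.

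Samples were grouped by their titles, and replicate numbers were taken from the titles. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, after filterByExpr on the groups and TMM normalization, with the robust quasi-likelihood F-test on genotype alone (two-sided) and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of F. Total estimated counts were 14677252 to 14949605 per sample, and a floor of 3 counts corresponded to 0.191 to 0.218 CPM in a sample. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of samples agreed within counting noise. The mean chi-square per gene with at least 20 counts, 1 under counting noise alone, was 2.32 to 2.79 between wild-type samples and 11.4 to 18.9 between mutants.

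Gene lists for pathways, tissues and cell types were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 46 lists, 45 had at least 5 tested members. They were tested with camera in limma 3.58.1 (preset correlation 0.01), with an estimated correlation and with fry as alternatives. Named genes are pikfyve, then the 12 highest and 12 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean count of at least 50 and no overlap between the genotypes. Names that are only clone or locus identifiers were left out and counted. For each list past the test, or with at least 3 members past the gene threshold, up to 4 members with the smallest p could be named, 2 in each direction where both exist. Alternatives were other scalings, other filters, the replicate number as a block, each sample left out in turn, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in at least 3 samples, and other thresholds. Scaling by library size alone and offsets for transcript length were added after the data were seen. The labels do not say that replicate numbers mark shared animals, litters or days.

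The procedure was tested on simulated counts for the pikfyve-delta8 against wild type comparison, with 200 changed genes. Among 20892 genes in the fit, 96% of 50 genes raised 2-fold and 100% of 50 genes raised 4-fold were recovered, as were 100% of 50 genes lowered to 0.5 and 100% of 50 lowered to 0.25 of their level. Of 20692 unchanged genes in the fit 9 were called, and the list test called 1 of 1 raised list and 0 of 40 unchanged lists. Changed genes were drawn only from genes with a mean count of at least 50, so recovery at lower counts was not tested. The raised list held only such genes, each raised 2-fold. Simulated genes varied independently of each other and with the same dispersion in both genotypes. The simulation therefore did not test lists whose members vary together, a larger spread among mutants or as many changed genes as in the data. Figures were drawn with matplotlib 3.10.9.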

Results

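RNA sequencing was compared between 3 wild-type zebrafish samples and 3 samples homozygous for pikfyve-delta8, a CRISPR/Cas9 allele. Pikfyve is the lipid kinase that phosphorylates a phosphoinositide on late endosomes and lysosomes, and fish with this allele are described as deficient in its kinase domain. The labels name neither the tissue nor the age of the fish. They do not say that the samples of a group came from separate animals or pools, so the p-values measure the spread between these samples, which may be technical. Total estimated counts ranged from 14677252 to 14949605 per sample over 25645 genes, so 1 count corresponded to 0.0635 to 0.0728 CPM (counts scaled to library size and TMM factor) after filtering. The first principal component of log2 CPM held 73.7% of the variance and separated the genotypes. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.991 to 0.992 between wild-type samples, 0.975 to 0.980 between mutant samples and 0.925 to 0.939 between genotypes. The mutant samples therefore differed more among themselves than the wild-type samples did. Expression values below are CPM as mean ± SD with n = 3 per genotype, given from wild type to mutant. Log2 fold changes are mutant minus wild type ± SE. For each gene named below as risen or fallen, all 3 samples of one genotype lay above all 3 of the other.

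The question posed by the design was how the transcriptome of fish homozygous for this allele differed from that of wild-type fish. The targeted gene was examined first. The pikfyve transcript (Gene ID 337690) was present in every sample, at 56.6, 53.8 and 52.1 CPM in the wild-type samples and at 61.2, 63.2 and 73.6 CPM in the mutants. Its log2 fold change was 0.29 ± 0.09, higher in all 3 mutants than in all 3 wild-type samples (edgeR quasi-likelihood test, adjusted p = 0.0209). A gene total does not read the edited bases, so this level does not check the genotype labels. The call was lost with upper-quartile scaling (adjusted p = 0.0639) and with library size alone (adjusted p = 0.270). It was also lost on the FPKM scale (adjusted p = 0.281), without wild type replicate 2 (adjusted p = 0.0778) and without wild type replicate 3 (adjusted p = 0.0958). The log2 fold change was 0.19 without pikfyve-delta8 replicate 3, and adjusted p over all alternatives ran from 0.000902 to 0.281.

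The mutants had higher transcript levels of lysosomal, inflammatory, neutrophil, sterol synthesis and unfolded protein response genes, and lower levels of photoreceptor, neuron, cell cycle and red blood cell genes. These groups passed camera's list test with a preset correlation, and none of them passed it with an estimated correlation (lowest adjusted p = 0.121). Of 21104 genes tested, 10140 differed at an adjusted p under 0.05, 5295 higher and 4845 lower in the mutants. Of these, 2787 also changed at least 2-fold, 1569 upwards and 1218 downwards. The 3 samples of one genotype lay entirely above those of the other for 58.8% of the tested genes, against 10% by chance. The split into higher and lower genes depended on the scaling, with 3824 higher and 6561 lower when counts were scaled by library size alone, a setting chosen after the data were seen. That setting moved the median log2 fold change of all genes to -0.14, from 0.0039 with TMM, and fold changes are therefore relative to the TMM reference.

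**Figure D1:**
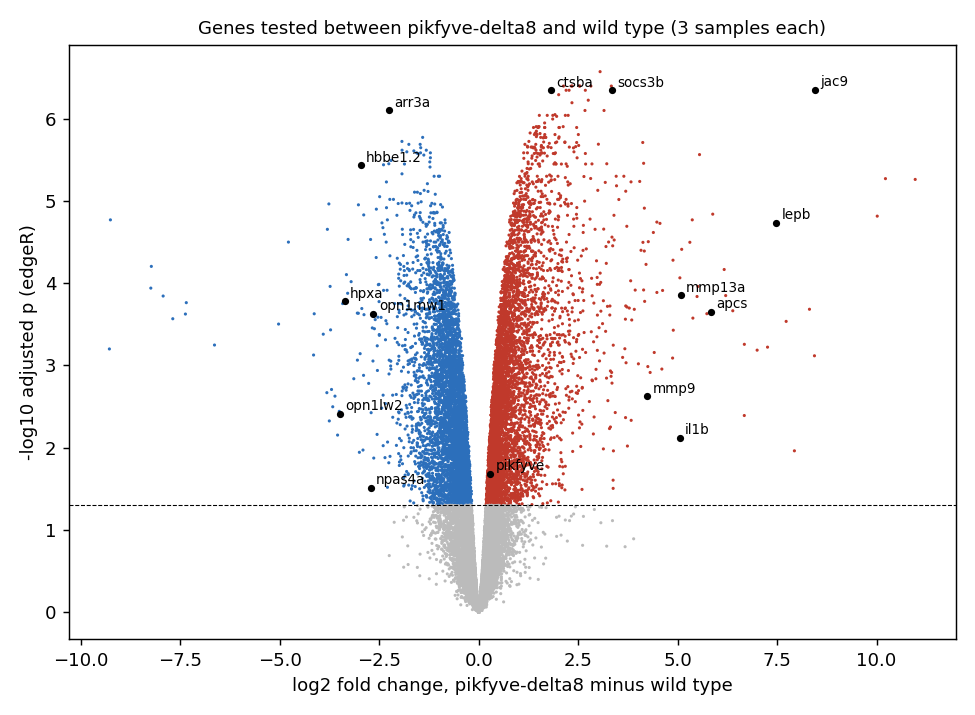
Each point is 1 of the 21104 genes tested, placed by its log2 fold change (pikfyve-delta8 minus wild type, 3 samples each) and the -log10 of its adjusted p from edgeR's quasi-likelihood test. Red genes were higher and blue genes lower at an adjusted p under 0.05 (dashed line), 5295 and 4845 genes, and black points carry gene names. The horizontal position of genes near 0 counts in one genotype, such as jac9, depends on the fitted prior count.

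The 12 most strongly raised named genes included cytokines, a chemokine and matrix proteases of inflammation. Transcripts of il1b, a pro-inflammatory cytokine, rose with a log2 fold change of 5.05 ± 0.88 and those of cxcl8b.1, a neutrophil chemoattractant, from 2.33 ± 0.287 to 49.7 ± 23.8 CPM. The cytokine gene il11a rose from 0.492 ± 0.208 to 17.1 ± 6.29 CPM. The matrix metalloproteinase genes mmp13a and mmp9 rose from 5.28 ± 1.00 to 178 ± 65.5 CPM and from 18.5 ± 1.65 to 348 ± 175 CPM. Leptin b (lepb, Gene ID 564348) rose from 0.150 ± 0.0742 to 28.2 ± 10.4 CPM, and the pentraxin gene apcs (Gene ID 792467) from 3.69 ± 0.717 to 212 ± 99.5 CPM. The transcription factor gene batf2 rose from 0.363 ± 0.160 to 10.9 ± 7.02 CPM. The membrane protein genes ms4a17a.12 and ms4a17a.2 rose by 5.37 ± 0.43 and 4.55 ± 0.36 on the log2 scale. No malb read was counted in the wild-type samples, whereas the mutants held 368 counts in total, which is at least 136-fold higher against a floor of 3 counts over the wild-type group. The lectin gene jac9 had 2 counts over the wild-type samples and 759 over the mutants, a ratio of 420 with an exact 95% counting interval of 116 to 3475, and its estimates were not whole numbers. Adjusted p for these 12 genes lay between 4.42e-07 and 0.00761 (edgeR). Without pikfyve-delta8 replicate 2 the log2 fold changes of il1b and batf2 were 4.26 and 4.22, against 5.05 and 4.87 with all samples. With a pseudocount of 1 on the FPKM scale 8 of these 12 genes moved toward 0 by over 1.5-fold. Their log2 fold changes were then 3.57 for il1b, 5.68 for lepb, 2.32 for il11a, 2.14 for batf2, 3.04 for ms4a17a.12, 3.31 for ms4a17a.2, 4.07 for jac9 and 3.81 for malb. With a pseudocount of 0.1 they were 4.27 for il11a, 3.98 for batf2, 6.87 for jac9 and 7.04 for malb, and limma-voom gave 8.06 for malb. A further 7 genes named only by clone or locus identifiers rose more than the 12th of these.

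Among the 12 most strongly lowered named genes, 5 encode proteins of cone or rod phototransduction. The red cone opsin gene opn1lw2 (Gene ID 436716) fell from 824 ± 75.6 to 73.0 ± 46.3 CPM, the green cone opsin gene opn1mw1 from 759 ± 46.8 to 121 ± 45.5 CPM and the ultraviolet cone opsin gene opn1sw1 (Gene ID 30582) from 2290.4 ± 38.9 to 424 ± 109 CPM. The photoreceptor kinase genes grk7a and grk1b fell from 115 ± 2.89 to 19.9 ± 7.48 CPM and from 40.7 ± 2.47 to 6.81 ± 2.75 CPM. The embryonic globin gene hbbe1.2 fell from 393 ± 37.6 to 50.2 ± 10.8 CPM, and hpxa, which encodes a hemopexin that binds heme, from 16.3 ± 3.01 to 1.58 ± 0.955 CPM. The proteasome subunit gene psmb10 fell from 7.13 ± 2.27 to 1.24 ± 0.301 CPM, lgals3bp.1 from 7.95 ± 0.391 to 1.33 ± 0.334 CPM and the protocadherin gene pcdh1g22 with a log2 fold change of -2.55 ± 0.35. The hatching enzyme gene he1.2 fell from 8.98 ± 1.59 to 0.787 ± 1.06 CPM, with a log2 fold change of -3.51, or -5.61 without pikfyve-delta8 replicate 1. The neuronal activity gene npas4a fell with a log2 fold change of -2.72 ± 0.70 (adjusted p = 0.0305), but its call was lost without wild type replicate 1 (adjusted p = 0.0774), wild type replicate 2 (adjusted p = 0.0823) or pikfyve-delta8 replicate 1 (adjusted p = 0.0842), and its adjusted p ran from 0.00117 to 0.0842 over all alternatives. The log2 fold change of npas4a was -3.51 without pikfyve-delta8 replicate 2. Without pikfyve-delta8 replicate 1 the log2 fold change of opn1lw2 was -4.13, against -3.50. With a pseudocount of 1 on the FPKM scale 3 of the 12 moved toward 0 by over 1.5-fold, hpxa to -2.63 from -3.37, lgals3bp.1 to -1.77 from -2.57 and pcdh1g22 to -1.91 from -2.55. With limma-voom and with a pseudocount of 0.1 he1.2 stood at -4.32 and -4.40. Adjusted p for the 12 genes lay between 3.67e-06 and 0.0305. Estimates for opn1lw2, hbbe1.2, he1.2, lgals3bp.1 and pcdh1g22 were not whole numbers in some samples, so reads shared with similar genes were divided between them and these levels are uncertain. A further 10 genes named only by clone or locus identifiers fell more than the 12th.

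Of 45 gene lists with at least 5 tested members, 21 were higher and 4 lower in the mutants in camera's competitive test with a preset correlation of 0.01. None of these 25 calls held when the correlation between genes was estimated (0 lists at an adjusted p under 0.05, 8 at an unadjusted p under 0.05). Calls were also lost for lists whose estimated correlation was below the preset, such as endothelial and mural genes (0.0097) and p53 targets (0.0059). A high correlation between members therefore does not account for every lost call. Other splits of the 6 samples gave as many as 28 lists. Each of those splits set unequal numbers of the genotypes against each other, so part of the genotype difference remained in it. In fry's self-contained test, which does not compare a list with other genes, 30 lists passed. They were these 25 and the lists of retinal pigment epithelium (adjusted p = 0.0188), kidney (adjusted p = 0.0189), myelinating glia (adjusted p = 0.0297), epidermis (adjusted p = 0.0362) and oocyte and germ line (adjusted p = 0.00390). The counts of members that rose or fell come from edgeR's gene-wise test. With library size alone every list median lay about 0.14 lower, so that it was 0.18 for V-ATPase subunits, 0.23 for autophagy, 0.20 for endosomal sorting, 0.25 for p53 targets, 0.15 for oxidative stress, 0.12 for clock genes and 0.19 for liver genes, each of which was higher by over 1.5 times with TMM.

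Photoreceptor genes fell as a group. Of 71 tested genes of rod and cone phototransduction, 62 fell and 1 rose (1 higher and 62 lower adjusted over the list alone), with a median log2 fold change of -1.34 (camera adjusted p = 1.41e-33, and adjusted p = 0.217 with an estimated correlation). The cone arrestin gene arr3a fell from 475 ± 38.4 to 98.7 ± 9.92 CPM and the phosducin gene pdcb from 89.3 ± 5.85 to 32.5 ± 2.16 CPM. The exception was impg2b, a gene of the matrix between photoreceptors, at 44.3 ± 5.61 to 56.5 ± 4.36 CPM, whose call was lost without wild type replicate 2 (adjusted p = 0.0850) or wild type replicate 3 (adjusted p = 0.0616) and with library size alone (adjusted p = 0.181), with a range of 0.000848 to 0.253 over all alternatives. Of 27 genes of the retinal pigment epithelium and visual cycle, 4 rose and 13 fell (4 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.0692), among them rlbp1a, which encodes a retinaldehyde-binding protein, from 34.7 ± 2.54 to 17.7 ± 3.58 CPM. That list was called lower without wild type replicate 2 (adjusted p = 0.0490), without pikfyve-delta8 replicate 1 (adjusted p = 0.00942), with no filter on low counts (adjusted p = 0.0472) and with length offsets (adjusted p = 0.0381), with a range of 0.00942 to 0.442 over all alternatives. Genes of the lens gave another result. Of 13 alpha and beta crystallin genes 6 rose and 1 fell (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.153), and crybb1 rose from 1109 ± 102 to 1873 ± 355 CPM. Without pikfyve-delta8 replicate 3 the list was called higher (adjusted p = 0.0136, range 0.0136 to 0.873 over all alternatives). Of 32 gamma crystallin genes 9 rose and 2 fell (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.361), with a median of 0.19 and a mean of -0.10, opposite in sign. That mean was -0.0038 with the member at 0 counts in one genotype set to its bound. Of 33 genes of lens fibers and their regulators 7 rose and 3 fell (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.903).

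Neuron genes fell without exception among the members that passed the test. Of 73 tested, 65 fell and 0 rose (0 higher and 68 lower adjusted over the list alone), with a median of -0.90 (camera adjusted p = 1.98e-24, and adjusted p = 0.288 with an estimated correlation). The microtubule-associated gene map1b fell from 55.9 ± 3.60 to 18.9 ± 1.71 CPM, the synaptic vesicle gene syn1 from 111 ± 6.25 to 39.9 ± 6.06 CPM and the GABA transporter gene slc6a1b from 158 ± 5.64 to 69.9 ± 7.93 CPM. Glial genes went both ways. Of 35 genes of radial glia, astroglia and Muller glia 10 rose and 14 fell (11 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.288). The glutamine synthetase gene glulb rose from 248 ± 11.2 to 524 ± 21.1 CPM, and the glutamate transporter gene slc1a2a fell from 31.8 ± 1.41 to 10.3 ± 2.03 CPM. That list was called lower without pikfyve-delta8 replicate 1 (adjusted p = 0.0147, range 0.0147 to 0.897 over all alternatives). Of 24 genes of myelinating glia 3 rose and 10 fell (3 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.201), with sox10 rising from 24.3 ± 0.672 to 39.4 ± 5.11 CPM and mag falling from 37.7 ± 2.32 to 19.5 ± 1.64 CPM.

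Cell cycle genes also fell, 50 of 61 tested with 0 higher (0 higher and 51 lower adjusted over the list alone), and their median was -0.75 (camera adjusted p = 5.56e-15, and adjusted p = 0.311 with an estimated correlation). The DNA methyltransferase gene dnmt1 fell from 81.3 ± 2.75 to 43.2 ± 1.77 CPM, and the replicative helicase genes mcm5 and mcm6 from 56.9 ± 0.694 to 27.9 ± 3.42 CPM and from 62.7 ± 0.698 to 32.0 ± 2.87 CPM. Among 29 erythroid genes 15 fell and 6 rose (6 higher and 15 lower adjusted over the list alone), with a median of -0.50 (camera adjusted p = 0.000179, and adjusted p = 0.364 with an estimated correlation). The red cell anion exchanger gene slc4a1a fell with a log2 fold change of -2.37 ± 0.18, whereas creg1, which encodes an endolysosomal glycoprotein, rose from 13.9 ± 0.616 to 30.5 ± 4.71 CPM.

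**Figure D2:**
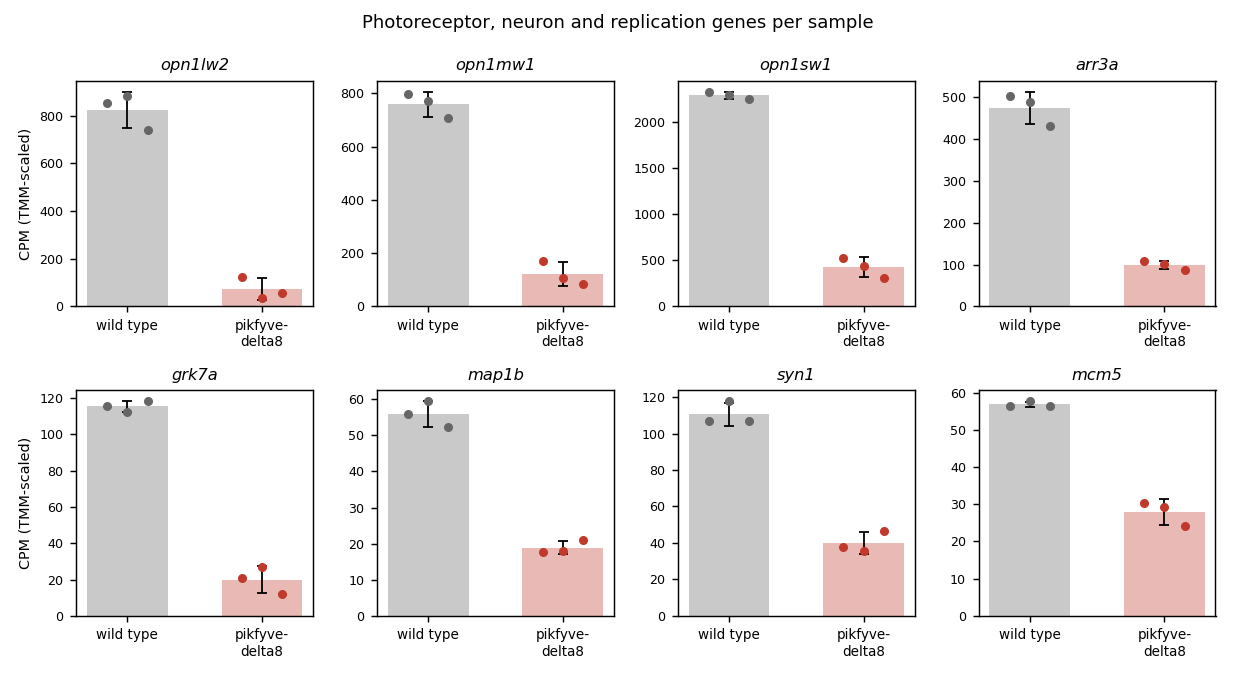
CPM (TMM-scaled) of 8 genes that fell, with 1 point per sample, bars at the mean and error bars of 1 SD (n = 3 per genotype, wild type in grey and pikfyve-delta8 in red). All 3 mutants lie below all 3 wild-type samples in each panel, for example arr3a at 98.7 CPM against 475 CPM on average.

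Lysosomal genes rose. Of 79 genes of lysosomal hydrolases and membrane proteins 58 rose and 1 fell (60 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.83 (camera adjusted p = 1.43e-24, and adjusted p = 0.121 with an estimated correlation). The cathepsin B gene ctsba rose from 173 ± 6.89 to 605 ± 10.9 CPM, a log2 fold change of 1.81 ± 0.07, and the cathepsin A gene ctsa from 40.2 ± 0.522 to 109 ± 4.33 CPM. The member that fell was the sorting receptor gene sort1b, at 32.9 ± 1.87 to 26.0 ± 1.72 CPM, whose call was lost without wild type replicate 3 (adjusted p = 0.0586, range 0.00131 to 0.0586 over all alternatives). Estimates for sort1b were not whole numbers, so its level is uncertain. Neutrophil markers moved with the genotype too, with a median of 1.55. Among 51 genes of the autophagy machinery 26 rose and 1 fell (29 higher and 1 lower adjusted over the list alone). Their median was 0.37 (camera adjusted p = 3.93e-05, and adjusted p = 0.266 with an estimated correlation). The autophagy receptor gene optn rose from 24.4 ± 1.21 to 57.8 ± 3.82 CPM and calcoco1b from 10.5 ± 1.07 to 47.4 ± 1.66 CPM, while the initiating kinase gene ulk1b fell from 19.9 ± 2.22 to 9.76 ± 4.13 CPM. Of 71 genes of endosomal sorting 40 rose and 7 fell (41 higher and 8 lower adjusted over the list alone). Their median was 0.34 (camera adjusted p = 1.86e-05, and adjusted p = 0.217 with an estimated correlation). The ESCRT gene vps37a rose from 38.5 ± 1.48 to 78.2 ± 1.90 CPM and the early endosome tether gene eea1 fell from 30.1 ± 1.43 to 22.7 ± 2.26 CPM, a log2 fold change of -0.41, or -0.25 with length offsets. Of 28 endolysosomal channel and transporter genes 14 rose and 3 fell (14 higher and 3 lower adjusted over the list alone). Their median was 0.44 (camera adjusted p = 0.00478, and adjusted p = 0.261 with an estimated correlation), with ostm1 rising from 7.46 ± 0.859 to 21.9 ± 1.14 CPM. The proton pump genes were divided. Of 26 V-ATPase subunit genes 16 rose and 5 fell (16 higher and 5 lower adjusted over the list alone). Their median was 0.32 (camera adjusted p = 0.0153, and adjusted p = 0.412 with an estimated correlation). Among them atp6v1ba rose from 154 ± 2.09 to 262 ± 3.47 CPM, while atp6v1b2 fell from 72.1 ± 5.18 to 36.2 ± 4.14 CPM and atp6v0a2a from 17.1 ± 0.494 to 6.15 ± 0.603 CPM.

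The enzymes of phosphoinositide turnover as a list did not pass the test. Of 55 genes 14 rose and 11 fell (14 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.631). The partners of Pikfyve in its complex rose, vac14 from 26.4 ± 1.05 to 61.8 ± 4.70 CPM and fig4a from 10.3 ± 1.07 to 20.6 ± 1.41 CPM, while the phosphatase gene mtmr7b fell from 25.7 ± 0.591 to 15.6 ± 2.32 CPM.

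The inflammatory, neutrophil, macrophage and interferon lists were called higher, and the lymphocyte list was not. These lists overlap, for example in mmp9 and mmp13a, which are on both the inflammatory and the neutrophil list. Of 42 tested inflammatory cytokines and NF-kB targets 32 rose and 1 fell (33 higher and 2 lower adjusted over the list alone), with a median of 1.39 (camera adjusted p = 1.16e-14, and adjusted p = 0.266 with an estimated correlation). The cytokine signalling inhibitor gene socs3b rose from 20.4 ± 3.55 to 207 ± 17.7 CPM, and the chemokine gene ccl34b.1, also a macrophage marker, fell from 3.35 ± 1.07 to 0.356 ± 0.0787 CPM. Of 18 neutrophil genes 15 rose and 0 fell (15 higher and 0 lower adjusted over the list alone). Their median was 1.55 (camera adjusted p = 1.11e-14, and adjusted p = 0.217 with an estimated correlation), and the risers included the protease gene npsn, from 8.66 ± 1.02 to 58.4 ± 5.60 CPM, and the lysozyme gene lyz, with a log2 fold change of 1.74 ± 0.10. Of 36 genes on the macrophage and microglia list 23 rose and 5 fell (24 higher and 7 lower adjusted over the list alone). Their median was 0.89 (camera adjusted p = 5.95e-06, and adjusted p = 0.311 with an estimated correlation). The raised members included the lysosomal enzyme gene hexb (estimates not whole and uncertain), from 74.7 ± 0.382 to 167 ± 0.671 CPM. The lowered members included the macrophage gene mpeg1.1, from 7.16 ± 0.663 to 1.97 ± 0.199 CPM, a log2 fold change of -1.86, or -1.23 with a pseudocount of 1 on the FPKM scale. For mpeg1.2, also on the list, the log2 fold change was 1.53 and did not pass the threshold (edgeR adjusted p = 0.0525). Of 50 interferon-stimulated genes in the data 29 passed the filter, and of these 22 rose and 0 fell (23 higher and 0 lower adjusted over the list alone). Their median was 1.07 (camera adjusted p = 5.63e-08, and adjusted p = 0.288 with an estimated correlation), with isg15 rising from 0.940 ± 0.158 to 10.4 ± 2.07 CPM (log2 fold change 3.45, or 2.52 with that pseudocount) and irf9 from 12.4 ± 0.996 to 40.9 ± 3.53 CPM. Of 29 lymphocyte genes in the data 14 passed the filter, and of these 4 rose and 1 fell (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.879).

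Lists of sterol synthesis and of several stress responses were called higher, and the heat shock list was not. Of 31 genes of cholesterol synthesis and SREBP targets 27 rose and 0 fell (28 higher and 0 lower adjusted over the list alone). Their median was 0.94 (camera adjusted p = 3.59e-09, and adjusted p = 0.311 with an estimated correlation). The sterol demethylase gene cyp51 rose with a log2 fold change of 2.05 ± 0.17 and the low-density lipoprotein receptor gene ldlra from 60.4 ± 1.46 to 174 ± 33.6 CPM. Of 48 genes of the unfolded protein and integrated stress responses 31 rose and 1 fell (35 higher and 1 lower adjusted over the list alone). Their median was 0.58 (camera adjusted p = 5.15e-09, and adjusted p = 0.266 with an estimated correlation), with ddit3, a transcription factor of the stress response, rising from 43.8 ± 1.92 to 117 ± 9.00 CPM and the lipoprotein receptor gene vldlr falling with a log2 fold change of -0.68 ± 0.08. Of 34 p53 targets 19 rose and 5 fell (19 higher and 5 lower adjusted over the list alone). Their median was 0.39 (camera adjusted p = 0.00753, and adjusted p = 0.233 with an estimated correlation). The growth arrest gene gadd45aa rose from 11.8 ± 0.0465 to 27.0 ± 1.35 CPM and the DNA repair gene ddb2 fell from 40.7 ± 1.00 to 22.6 ± 1.49 CPM. Of 33 oxidative stress genes 21 rose and 4 fell (21 higher and 4 lower adjusted over the list alone). Their median was 0.30 (camera adjusted p = 0.00753, and adjusted p = 0.251 with an estimated correlation), with nfe2l2a, which encodes NRF2, rising from 142 ± 6.38 to 271 ± 7.92 CPM and catalase (cat) falling from 269.9 ± 14.9 to 161 ± 27.5 CPM. Of 55 glycolysis and hypoxia genes 24 rose and 6 fell (24 higher and 6 lower adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.000175, and adjusted p = 0.412 with an estimated correlation), and pfkfb3 rose from 48.4 ± 1.44 to 262 ± 48.0 CPM. That median was 0.09 with upper-quartile scaling and 0.01 with library size alone. Of 30 glucocorticoid-responsive genes 17 rose and 5 fell (17 higher and 5 lower adjusted over the list alone). Their median was 0.45 (camera adjusted p = 0.00207, and adjusted p = 0.217 with an estimated correlation), and foxo1a rose from 41.3 ± 1.41 to 120.0 ± 8.72 CPM. Of 33 heat shock genes 3 rose and 1 fell (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.153). Their median was nonetheless 0.54 and their mean 0.95, and the median ran from 0.12 to 0.71 over all alternatives. The heat shock list was called higher without pikfyve-delta8 replicate 1 (adjusted p = 0.0333) or pikfyve-delta8 replicate 3 (adjusted p = 0.0255), with a range of adjusted p of 0.0255 to 0.873 over all alternatives.

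**Figure D3:**
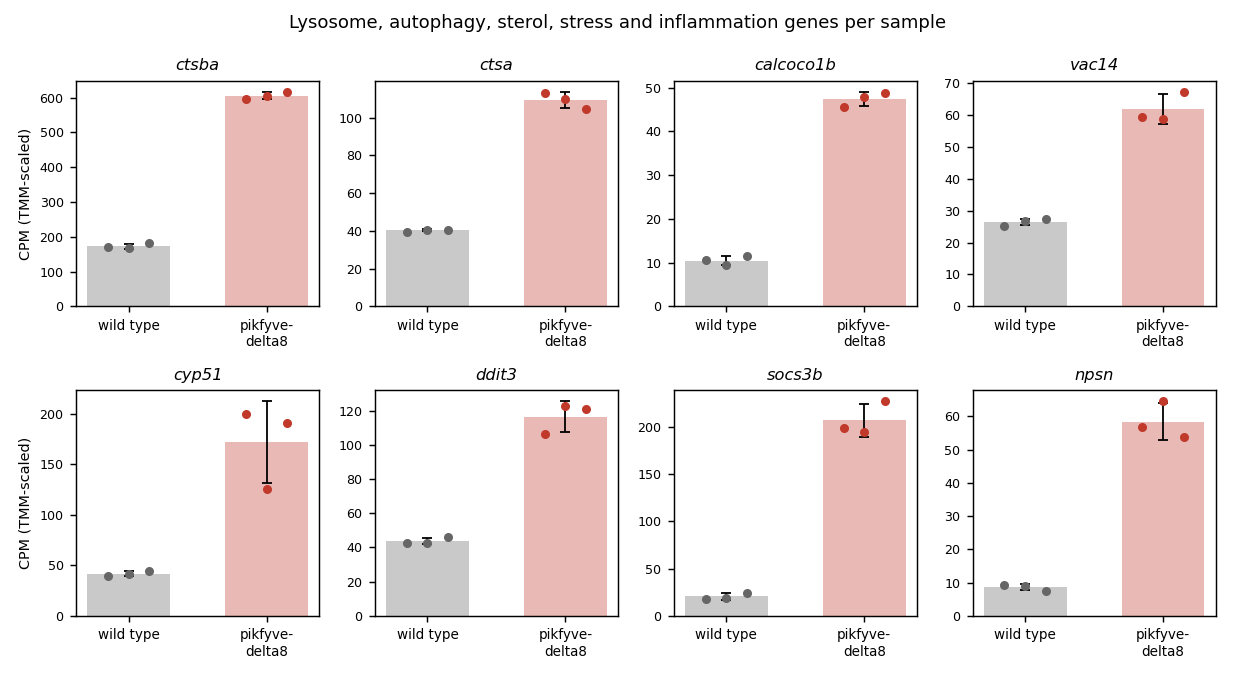
CPM (TMM-scaled) of 8 genes that rose, with 1 point per sample, bars at the mean and error bars of 1 SD (n = 3 per genotype, wild type in grey and pikfyve-delta8 in red). All 3 mutants lie above all 3 wild-type samples in each panel, for example ctsba at 605 CPM against 173 CPM on average.

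Of 87 liver plasma protein and hepatocyte genes 48 rose and 11 fell (48 higher and 11 lower adjusted over the list alone). Their median was 0.34 (camera adjusted p = 1.72e-11, and adjusted p = 0.233 with an estimated correlation). The complement gene cfb rose from 59.5 ± 4.70 to 346 ± 28.4 CPM, and the apolipoprotein gene apoba fell from 371 ± 15.3 to 188 ± 18.2 CPM. Of 37 endothelial and mural genes 22 rose and 2 fell (22 higher and 3 lower adjusted over the list alone). Their median was 0.63 (camera adjusted p = 4.85e-05, and adjusted p = 0.217 with an estimated correlation), with the lymphatic gene lyve1a rising with a log2 fold change of 2.67 ± 0.12. Of 30 exocrine pancreas genes 17 rose and 3 fell (17 higher and 3 lower adjusted over the list alone). Their median was 0.50 (camera adjusted p = 0.00397, and adjusted p = 0.707 with an estimated correlation), with the elastase gene cela1.6 rising from 1362 ± 79.2 to 2679 ± 34.2 CPM. Of 42 clock genes 20 rose and 10 fell (21 higher and 10 lower adjusted over the list alone). Their median was 0.26 (camera adjusted p = 0.0288, and adjusted p = 0.510 with an estimated correlation), and nfil3 rose from 44.5 ± 3.88 to 131 ± 4.68 CPM. That clock call was lost without pikfyve-delta8 replicate 1 (adjusted p = 0.0510) or pikfyve-delta8 replicate 3 (adjusted p = 0.0670), with library size alone (adjusted p = 0.0550) and with the stricter filter (adjusted p = 0.0580), with a range of 0.00316 to 0.510 over all alternatives. Of 36 immediate early genes 17 rose and 10 fell (17 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.050, just above the threshold), with jun rising from 161 ± 2.55 to 327 ± 10.8 CPM and klf2a falling from 93.7 ± 14.6 to 46.3 ± 9.24 CPM. The list was called higher without pikfyve-delta8 replicate 1 (adjusted p = 0.0218) or pikfyve-delta8 replicate 3 (adjusted p = 0.0110), with upper-quartile scaling (adjusted p = 0.0412), with library size alone (adjusted p = 0.0342) and with no filter (adjusted p = 0.0310), with a range of 0.0110 to 0.712 over all alternatives.

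Of 94 genes matching the ribosomal protein pattern 44 rose and 2 fell (45 higher and 2 lower adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.00367, and adjusted p = 0.798 with an estimated correlation). That pattern also took in 11 ribosomal S6 kinase genes, and both genes that fell, rps6ka1 and rps6kl1, named after their values were seen, were among them. Without these kinases 43 of 83 genes rose and 0 fell, with a median of 0.23, and the median of the full list was 0.08 with library size alone. Of 5 histone genes, a list kept as a sign of RNA quality, 3 rose and 0 fell (3 higher and 0 lower adjusted over the list alone). Their median was 0.58 (camera adjusted p = 0.00397, and adjusted p = 0.266 with an estimated correlation). The histone gene h1-10 rose from 93.5 ± 4.78 to 295 ± 25.1 CPM. With no filter on low counts the list median was 0.89 and the call was lost (camera adjusted p = 0.0521, range 0.000606 to 0.266 over all alternatives). No gene of the table matched the list of mitochondrially encoded transcripts.

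The remaining lists did not pass camera's test with the preset correlation. Among 46 epidermal genes 18 rose and 10 fell (18 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.150), with epcam rising from 141 ± 9.66 to 596 ± 107 CPM and ppl falling with a log2 fold change of -0.63 ± 0.08. That list was called higher without pikfyve-delta8 replicate 3 (adjusted p = 0.0370, range 0.0362 to 0.712 over all alternatives). Among 51 intestinal genes 17 rose and 9 fell (17 higher and 10 lower adjusted over the list alone; adjusted p = 0.233). Among 24 kidney genes 8 rose and 4 fell (9 higher and 5 lower adjusted over the list alone; adjusted p = 0.292). For pigment cells 10 of 30 rose and 5 fell (10 higher and 5 lower adjusted over the list alone; adjusted p = 0.507), and for skeletal muscle 22 of 70 rose and 11 fell (22 higher and 10 lower adjusted over the list alone; adjusted p = 0.532). For heart muscle 4 of 19 rose and 1 fell (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.995), with a median of -0.12 and a mean of 0.08. For the extracellular matrix 8 of 60 rose and 9 fell (8 higher and 8 lower adjusted over the list alone; adjusted p = 0.631), with fbn1 rising from 18.7 ± 1.51 to 39.9 ± 2.62 CPM and tnc falling from 182 ± 5.30 to 85.5 ± 17.9 CPM. Genes of nuclear-encoded oxidative phosphorylation gave 10 higher and 13 lower of 100 (8 higher and 6 lower adjusted over the list alone; adjusted p = 0.431). Proteasome subunits gave 1 higher and 3 lower of 41 (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.519), with a median of 0.0078, below 0 under the other scalings, and a mean of -0.069. Oocyte and germ line genes gave 1 higher and 1 lower of the 16 that passed the filter, out of 48 in the data (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.774).

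**Figure D4:**
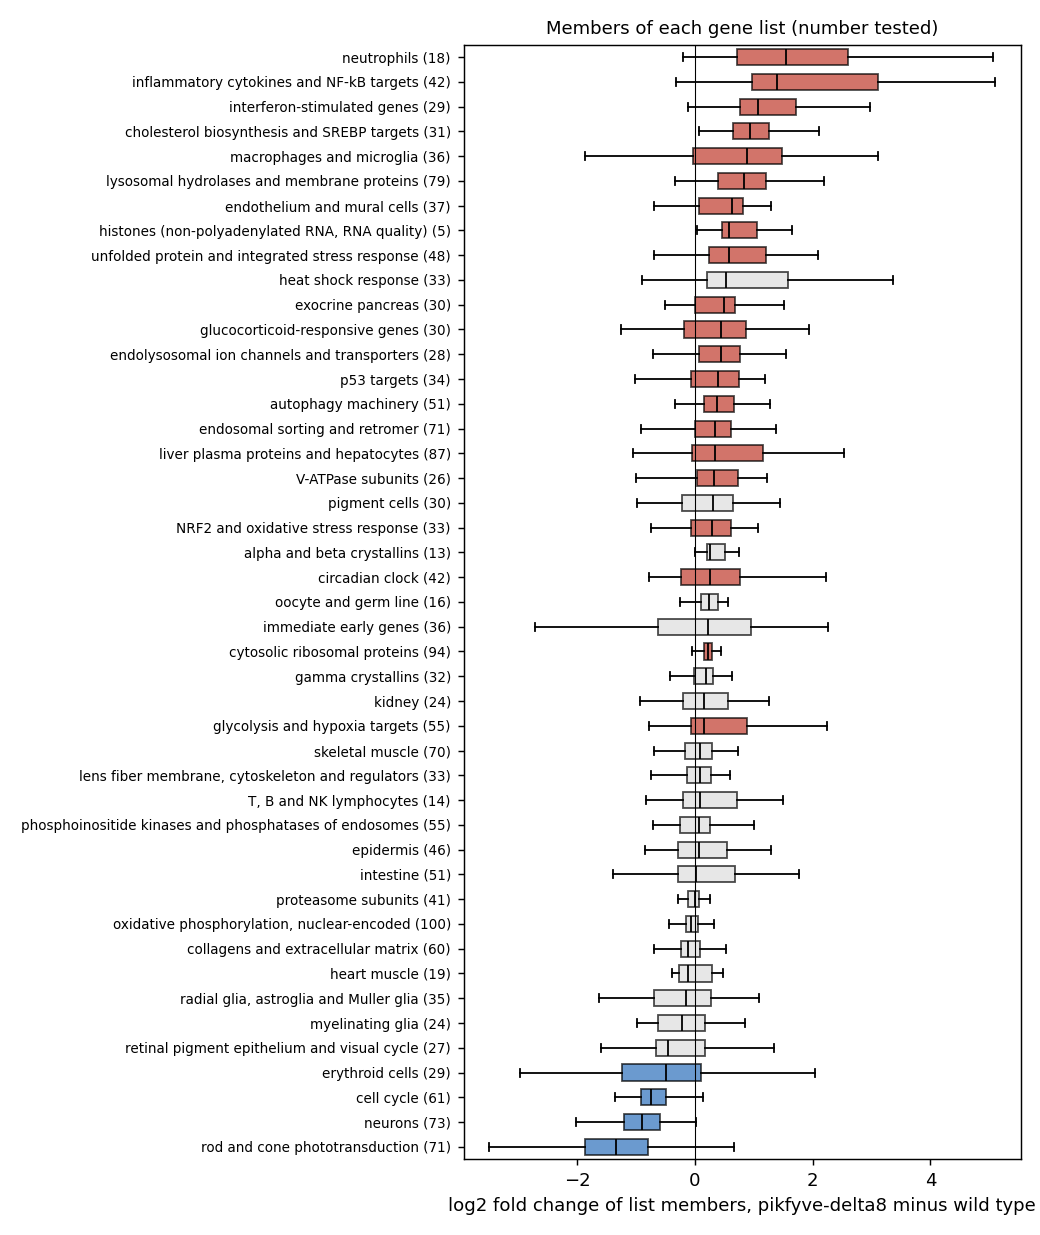
Log2 fold changes (pikfyve-delta8 minus wild type) of the members of each of the 45 gene lists, with the number tested in brackets; boxes span the quartiles, the line is the median and whiskers reach the last value within 1.5 box lengths. Red lists were called higher (21) and blue lists lower (4) by camera with a preset correlation, and grey lists were not called; phototransduction has the lowest median (-1.34) and neutrophils the highest (1.55).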

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

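Scaling by library size alone and the length offsets were chosen after the data were seen. The count of 10140 genes stayed within 1.5 times under all alternatives except the fold minimum, which left 2787 genes. It was 10139 with DESeq2's size factors, 10239 with upper-quartile scaling, 10215 without a filter, 8510 with the stricter filter, 8940 with DESeq2's Wald test (4 genes without an adjusted p) and 7767 to 10982 with a sample left out. No gene called under these alternatives had the opposite direction to its call in the report. The share of higher genes moved by over 10 percentage points with library size alone (3824 higher, 6561 lower) and with limma-trend, which has no composition scaling, on log2(FPKM + 1) (3569 higher, 6250 lower) and log2(FPKM + 0.1) (3566 higher, 6176 lower). The count of 25 lists was 0 with an estimated correlation, 30 with fry and 25 to 28 with a sample left out. Of the 25 lists, 23 kept their call in each alternative that tested them other than the estimated correlation; the circadian and histone lists did not. The pikfyve log2 fold change of 0.29 kept its sign throughout. It passed the threshold no longer with upper-quartile scaling (0.22), library size alone (0.15), log2(FPKM + 1) (0.14) and log2(FPKM + 0.1) (0.15), and it ran from 0.19 to 0.34 with a sample left out. Library size alone lowers the genes by nearly the same amount (quartiles of the shift -0.15 and -0.14), whereas log2(FPKM + 1) lowers 85.9% of 18822 genes and raises 14.1% (quartiles -0.17 and -0.08). Causes were not tested. Of 184 further genes open to naming, 172 kept their call in each alternative that tested them and 0 reversed. With log2(FPKM + 1), 20 of the 180 tested moved by over 1.5-fold, and 169 of the 184 were tested in all 17. These 184 were picked for large fold changes or small p, so they do not show how stable other calls are. Of all 10140 calls, 7659 to 7787 recurred in the same direction without a wild-type sample and 8946 to 9526 without a mutant sample. On the FPKM scale, where fewer genes were tested, 8000 to 8015 recurred.

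With the replicate number as a replicate block, 9575 genes and 25 lists were called and the pikfyve log2 fold change was 0.28 (adjusted p = 0.0391). Samples with the same number did not deviate together (correlations of -0.075, 0.050 and -0.048), not every sample correlated best with its own number, and the numbers are not taken to pair the samples. At this depth a gene without a count in a sample lies below about 0.2 CPM.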

Other observations

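All tests in this part were chosen after the data were seen, except the counts over other splits of the samples. Genes were also grouped by the leading letters of their symbol, with the ms4a17a genes set apart by hand as a group of their own. The 255 groups with at least 10 tested genes were compared with camera (preset correlation). Of these, 10 were higher and 14 lower at an adjusted p under 0.05, and 0 with an estimated correlation (9 at an unadjusted p under 0.05). The ms4a17a genes, which encode membrane-spanning proteins, stood first, with 12 of 13 higher and 0 lower. Their median log2 fold change was 2.34 (adjusted p = 6.28e-10, and adjusted p = 0.920 with an estimated correlation). That group was set after the data were seen, and ms4a17a.12 and ms4a17a.2 are among the 12 most strongly raised named genes. Its rank is therefore no independent support for their rise. Interleukin and interleukin receptor genes rose in 23 of 35 cases and fell in 2 (median 0.97, adjusted p = 7.12e-06, and adjusted p = 0.920 with an estimated correlation). Interferon regulatory factor genes rose in 10 of 15 cases and fell in 1 (median 0.97, adjusted p = 0.000202, and adjusted p = 0.920 with an estimated correlation).

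Protocadherin genes, which encode neuronal adhesion proteins, fell in 35 of 61 cases and rose in 1 (median -0.54, adjusted p = 8.43e-06, and adjusted p = 0.920 with an estimated correlation). Estimates of 43 of these 61 genes were not whole numbers, so reads shared within the clusters make single members uncertain. Kinesin genes fell in 28 of 42 cases and rose in 2 (median -0.58, adjusted p = 0.000185, and adjusted p = 0.920 with an estimated correlation). Metabotropic glutamate receptor genes fell in 10 of 10 cases (median -0.86, adjusted p = 0.00786, and adjusted p = 0.920 with an estimated correlation). Voltage-gated calcium channel genes fell in 17 of 23 cases (median -0.67, adjusted p = 0.000416, and adjusted p = 0.920 with an estimated correlation). The medians of these 7 groups kept their sign under all 4 scalings. This tested little, since library size alone shifted genes by nearly the same amount (median -0.14), which is small beside these medians.

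The real grouping gave 10140 genes, and the highest of the other splits gave 0. For gene lists the real grouping gave 25 and the highest of the others 28, so 2 of the 10 splits reached the real count for lists and 1 of the 10 for genes. With 10 splits no share under 0.05 can be reached. Each other split set unequal numbers of the genotypes against each other, and so held part of the genotype difference between its groups and part within them. These counts therefore do not show what groupings without a genotype difference would give.

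Photoreceptor and neuron transcripts were lower together. Loss of whole eyes is argued against by the alpha and beta crystallins, whose lower quartile was 0.21, above the upper quartile of phototransduction genes at -0.79. Transcript length bias is argued against as the whole cause, since the phototransduction median was -1.34 with the length offsets. Its list was still called with them (camera with the preset correlation, adjusted p = 9.70e-34). Without offsets and with an estimated correlation its camera adjusted p was 0.217. Against a smaller share of all neural tissue, the median was -0.15 for radial glia, astroglia and Muller glia genes (upper quartile 0.28) and -0.22 for myelinating glia genes, but -0.90 for neuron genes. Without pikfyve-delta8 replicate 1 the first of these medians was -0.26 and that list was called lower (camera adjusted p = 0.0147). That list also holds genes of other lists, such as glulb, which rose and is on the glucocorticoid list. Its median may therefore not follow neural tissue alone. A smaller share of neural tissue stays open, as the lower quartiles of -0.69 and -0.63 of these glia genes lay below the upper quartile of neuron genes at -0.60. A lower output or number of photoreceptors and neurons in the mutants is a hypothesis that these bulk values cannot separate from it.

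Lysosomal transcripts were higher. The choice of TMM over library size is argued against as the whole cause, since the lysosomal median was 0.69 with library size alone. That setting lowers all genes by nearly the same amount, so it does not test other effects of RNA composition. The fixed macrophage list of 36 genes shares 3 genes with the lysosomal list, among them hexb, so the lists are not independent. An influx of macrophages stays open, since this fixed list had 23 higher and 5 lower (median 0.89). In contrast, 10 restricted markers among its members had 0 higher and 4 lower (median -0.27). The most abundant of these 10, slc7a7 and mpeg1.2, stood at 49.8 ± 1.04 to 38.5 ± 7.41 CPM and 15.2 ± 0.757 to 43.8 ± 29.3 CPM. An influx of neutrophils, whose markers had a median of 1.55, and a response of lysosomal genes within the mutant cells stay open as well, as hypotheses.

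A group of 15 genes had at most 3 counts over one genotype and at least 20 in each sample of the other, 8 present in the mutants and 7 in the wild type. They include malb, jac8, jac9 and plac8.2 in the mutants and sult1st7 in the wild type, named after their values were seen, and jac8 and jac9 are neighbours in the GRCz12tu annotation. Estimates of 8 of the 15 were not whole, against 10.6% of 19341 other genes with such counts (Fisher's exact test, two-sided, p = 5.25e-05), a higher share, as reads split between similar copies would give. This says nothing of the other 7, whose estimates were whole. Linkage to pikfyve stays open, with 0 of the 10 genes placed in that annotation on its chromosome and 5 not placed, and so does a strain difference between the fish, which was not tested.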
